A study of Mus musculus with 16 samples.

How the data were processed

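Neuro 2a is a mouse neuroblastoma cell line. Cells were either left untreated (basal) or exposed to hydrogen peroxide, RNA was extracted with TRIzol, and abasic sites in the RNA were labelled with the aldehyde reactive probe (ARP), a biotin-bearing reagent that couples to the exposed aldehyde of a sugar that has lost its base. In each condition 1 portion of labelled RNA was hybridised without selection (Basal-total and Ox-total) and another was first captured on streptavidin beads (Basal-ARP and Ox-ARP), which gives 4 groups of 4 arrays. The dose and duration of the peroxide exposure are not given in the sources used here. Per the labels' protocols, amplified RNA was made with the Ambion TotalPrep kit, hybridised to Illumina mouse bead arrays and stained with Cy3-streptavidin. Whether this amplification represents histone transcripts and small nuclear RNAs as it does other transcripts was not tested.

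The deposited scanner table holds, for each of 25697 probes on each array, a bead intensity on a linear scale that is not normalized between arrays, and a detection p-value that the authors' software derived from negative control beads. The smallest step between these deposited p-values corresponds to 798 negative controls. GenomeStudio 2010.2 is named in the submitters' processing notes. The authors also deposited a table of processed intensity for the same arrays. Set against the scanner values, each column of that table was a linear function of the array's own signal with a mean of 376 in every column and column medians from 12.3 to 16.3, and 28.2% of its values lay below 0. It was used as an alternative, after a floor of 1 and log2. The intercept of that function points to a background subtraction, but which method was used stays unknown.

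Scanner intensities were background corrected and offset by 16 with the normexp function of limma 3.58.1 (R 4.3.3), with the negative control distribution estimated from the detection p-values, then quantile normalized and taken to log2. The offset and the correction draw the fold changes of dim probes towards 0. Quantile normalization gives every array the same distribution of values, so a difference between a captured and a total fraction is a shift in relative representation. The amount of RNA recovered from the beads was not measured by the arrays.

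Probes with a detection p-value under 0.01 on all 4 arrays of at least 1 group were kept, which left 10794 probes. Gene symbols came from the platform annotation: 23978 probes carried 1 symbol, 0 carried several and 1719 carried none. By gene identifier 23962 probes matched the RefSeq gene table of assembly GRCm38.p6, from which names and the genomic span of each gene were taken and no coordinates. A gene with several passing probes (1974 genes) was represented by the probe with the highest mean over all arrays. This gave 8072 features, 7464 named genes and 608 probes without a symbol, all called genes in the counts. Among genes with several called probes, 37 of 434 had probes called in opposite directions in Basal-ARP against Basal-total, 53 of 367 in Ox-ARP against Ox-total and 65 of 371 in Ox-ARP against Basal-ARP. Of the other probes of called genes, 85.7%, 79.0% and 74.6% had the same sign in these comparisons, in that order.

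A linear model with a mean per group was fitted to all 16 arrays with lmFit and eBayes in limma, with 12 residual and 5.37 prior degrees of freedom. From it, 5 differences were taken: 4 between pairs of groups, and the interaction, the change on capture with peroxide minus the change on capture without it. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all 8072. Values are given as log2 fold change ± limma's standard error, with 4 arrays per group throughout. The median standard error was 0.12 for a difference between 2 groups and 0.17 for the interaction. Where a gene was not detected on any array of a group, its change is given as at least N-fold. This sets the brighter group's mean over all its arrays against the dimmer group's mean of, per array, the higher of the probe's own value and the lowest value among detected probes.

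The following choices were made before the data were examined: the model, the alternatives, 31 gene lists and the rule for the genes named. The rule takes the 10 genes most raised and the 10 most lowered among those called and moved the same way in all 4 same-numbered comparisons, the 4 members of each list with the smallest p, and 7 stress and reference genes (Hmox1, Srxn1, Cdkn1a, Fos, Ddit3, Gapdh and Actb). Predicted genes and probes without a symbol that met the rule were left unnamed in the text, and some list members were left out for length. Lists were tested with camera in limma, with a preset correlation between genes of 0.01, and again with the correlation estimated from the arrays. At least 3 tested members were required, which left 27 lists. Of the others, the mitochondrial DNA list and the macrophage and blood cell list had 0 tested members, the glial list had 2 and the epithelial list had 1.

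The arrays lay on 2 chips, each with 2 arrays of every group, replicates 1 and 2 on 1 chip and 3 and 4 on the other. Because the chips were balanced, adding the chip as a block left fold changes as they were and altered only the spread. Same-numbered arrays of a captured and a total fraction deviated together from their group means (r from 0.29 to 0.638 without peroxide and from 0.145 to 0.711 with it, over genes). Same-numbered arrays also share a chip, which may add to these values. The captured array closest to a total array had its own number for 3 of 4 arrays without peroxide and 2 of 4 with it. In some alternatives and tests the replicate number was treated as a pairing of captured with total RNA. This assumption was read from the values because no label states it. The main model has no term for the pairing, so the main counts and p-values do not use it. It entered only alternative fits, the rule for the genes named and tests with splits of the arrays. Across treatments the numbers were not treated as pairs (r from -0.262 to 0.474 between total fractions and from 0.017 to 0.621 between captured fractions). The own number was closest for 0 of 4 total and 3 of 4 captured arrays, so a pairing between captured fractions is not excluded. Nothing in the labels says that the 4 replicates were separate cultures, so p-values measure only the spread between these arrays, which may be technical.

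Alternatives were median scaling, no normalization, cyclic loess, the authors' values, no background correction, other filters on dim probes, the mean of a gene's probes, trended and robust variance, chip or replicate as a block, each chip alone, and each array or replicate number left out. A brightness covariate, array weights and the replicate block within each treatment were added after seeing the data. The fit was tested on simulated data with 100 genes changed at each size among 8072. A change of 1 on the log2 scale was recovered for 97% of genes in Ox-total against Basal-total, 94% in Basal-ARP against Basal-total, 96% in Ox-ARP against Ox-total, 97% in Ox-ARP against Basal-ARP and 78% in the interaction, and a change of 0.5 for 54%, 57%, 57%, 65% and 16%. False calls numbered 8, 10, 17, 5 and 5 in the same order. The simulated noise was independent between genes and arrays, without pairs or chips. Fewer genes were changed than were called in both capture comparisons and between the captured fractions. The recovered shares may therefore not hold for the real comparisons. The number of arrays limits the precision.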

Results

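RNA of Neuro 2a cells was labelled with ARP and profiled before and after streptavidin capture, with and without peroxide. There were 16 arrays in 4 groups of 4. No group held RNA captured without ARP label. Retention on the beads without label therefore cannot be told apart from abasic sites in any comparison with a captured fraction. Array mean signals ran from 328 to 533, and between 10351 and 11068 of 25697 probes (40.3% to 43.1%) were detected per array. Group mean signals were 435 ± 65.6 in Basal-total, 461 ± 65.1 in Ox-total, 390 ± 71.7 in Basal-ARP and 441 ± 63.1 in Ox-ARP (SD, n = 4 arrays each). No arrays were identical, and every pair of arrays correlated at 0.95 or more over the tested genes. The first principal component held 37.7% of the variance and separated captured from total RNA, and the second held 21.5%. Within each chip the array positions were not shared between groups (0 positions held more than 1 group), so position and group cannot be told apart.

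**Figure D1:**
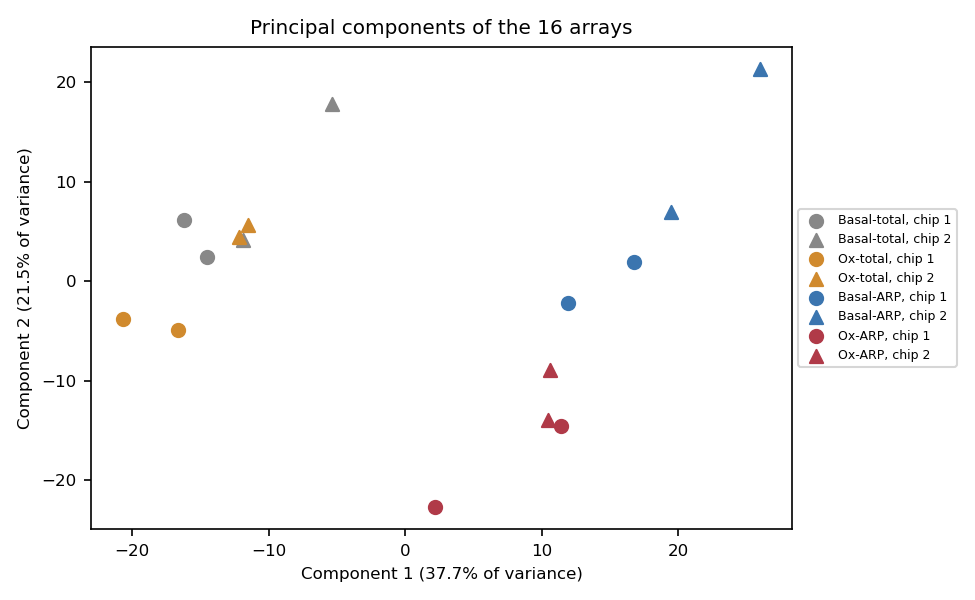
Scores of the 16 arrays on the first 2 principal components of normalized log2 values over the 8072 tested genes, with the share of variance on each axis, colours for groups, circles for chip 1 and triangles for chip 2. Component 1 (37.7%) parts captured from total RNA.

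The comparison of Ox-total with Basal-total asks how peroxide altered transcript levels before any capture. Only 25 of 8072 genes changed, 5 up and 20 down. Replication-dependent histone genes were among those raised: H4c12 rose by 0.75 ± 0.13 (adjusted p = 0.011) and H4c6 by 0.62 ± 0.12 (adjusted p = 0.041). Whether their probes follow the whole histone mRNA level was not tested. The raised genes also held Lrrc29 (0.95 ± 0.14, adjusted p = 0.0028, detected on 3 Basal-total arrays) and the zinc finger repressor gene Zbtb2 (0.49 ± 0.08). Tpt1, the gene of the translationally controlled tumor protein, was detected on 3 Ox-total arrays and 0 Basal-total arrays (at least 1.11-fold higher). The Tpt1 signal lay near the detection limit, and whether it reads the gene's main transcript was not tested. Rps15a, which encodes a protein of the small ribosomal subunit, fell by 1.11 ± 0.09 (adjusted p = 5.9e-06), the smallest p of the comparison among named genes.

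The other lowered genes included Plekha5 (-1.16 ± 0.14, adjusted p = 0.00096, detected on 1 Ox-total array), Nfkbiz, an inflammatory regulator of NF-kappaB (-0.83 ± 0.15), and the homeobox gene Zfhx3 (-0.79 ± 0.16, adjusted p = 0.041). Tdp1, whose enzyme removes stalled topoisomerase from DNA ends, was at least 1.49-fold lower, Prr15 at least 1.4-fold and Fcer2a at least 1.23-fold, each detected on 4 Basal-total arrays and 0 Ox-total arrays. Tardbp, which encodes the RNA-binding protein TDP-43, fell by 0.71 ± 0.12 (adjusted p = 0.0077) on its brightest probe, and Bace1, the beta-secretase gene, had -0.45 ± 0.12 (adjusted p = 0.16). Genes of the oxidative and DNA damage responses did not pass: Hmox1, the heme oxygenase gene, had 0.25 ± 0.10 (adjusted p = 0.41, higher in 4 of 4 same-numbered arrays). Srxn1 had -0.02 ± 0.12, Cdkn1a -0.04 ± 0.12, Fos 0.40 ± 0.13 (adjusted p = 0.24) and Ddit3 0.24 ± 0.16. Gapdh (0.03 ± 0.08) and Actb (-0.02 ± 0.08) did not pass either.

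As groups, 6 of 27 lists passed camera with the preset correlation after peroxide in total RNA, most of them through small shifts of many genes. Across all genes the change also followed genomic span (Spearman's rho -0.294 across 7460 genes, which are not independent replicates; 2 of 35 splits of the arrays gave a rho as far from 0). Without Basal-total replicate 3 rho was -0.195. With genes in 4 equal groups by span, medians ran from 0.07 in the shortest to -0.05 in the longest. Of 34 histone genes 2 rose, 0 fell and 32 did not pass, with a median of 0.33 (18 raised when adjusted over the list alone). H2bc18 (0.75 ± 0.16, adjusted p = 0.0505) and H4c11 (0.68 ± 0.15, adjusted p = 0.073) did not pass singly. The histone list had an adjusted p of 1.2e-12, against an adjusted p of 0.10 with an estimated correlation, and medians of 0.32 and 0.33 on the 2 chips. The mitochondrial ribosomal list (median 0.12, 0 of 70 passing, also 0 adjusted over the list alone) and the respiratory chain list (median 0.08, 0 of 72) shifted up. Mrps10 had 0.28 ± 0.11, Mrpl35 0.27 ± 0.10, Cox6a2 0.27 ± 0.12 and Ndufs3 0.19 ± 0.09. Their adjusted p-values were 1.9e-06 and 0.00084, or 0.45 and 0.58 with an estimated correlation. Chip medians were 0.13 and 0.12 for the former and 0.10 and 0.05 for the latter. Antioxidant and thiol enzymes shifted up (median 0.11, 0 of 21 passing, Glrx 0.24 ± 0.11, Sod2 0.15 ± 0.09). The adjusted p was 0.027, or 0.44 with an estimated correlation, and chip medians were 0.13 and 0.08. Lists of p53 targets and of genes with long mRNAs shifted down. The p53 list had a median of -0.08 over 19 genes with 0 passing (Mdm2 -0.22 ± 0.09, Sesn2 -0.39 ± 0.12). Its adjusted p was 0.017, or 0.10 with an estimated correlation, and its chip medians were -0.13 and -0.18. The long mRNA list had a median of -0.16 over 35 genes, of which Zfhx3 alone fell (Ank2 -0.40 ± 0.14, Plec -0.29 ± 0.10). Its adjusted p was 0.00018, or 0.50 with an estimated correlation, and its chip medians were -0.12 and -0.19. Each list's median was also set among 10000 random lists matched on genomic span, a step chosen after the values were seen. It lay at percentile 100 for histones, 99.98 for the mitochondrial ribosomal list, 98.6 for antioxidant enzymes and 91.4 for the respiratory chain, and at 0.38 for p53 targets and 0.07 for long mRNAs. For histones the match may not hold span equal. Their median span was 0.488 kb, against a median of 5.12 kb in the shortest of the 4 groups by span.

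The other 21 lists did not pass (adjusted p from 0.131 to 0.914), NRF2 targets among them (median 0.02). Some of these passed under other settings. The proteasome list passed with median scaling (adjusted p = 0.000735), no normalization (0.000886), cyclic loess (0.0117) and the authors' values (0.00052). Glycolysis passed with median scaling (0.00953), no normalization (0.000483) and the authors' values (0.0367), without replicate 4 (0.0462) and with array brightness as a covariate (0.0161, chosen after seeing the data). Tubulins and actin genes passed with median scaling (0.0245), no normalization (0.0313) and the authors' values (0.0414), and the cytosolic ribosomal and zinc finger lists with median scaling (0.032 and 0.0441). In limma 836 genes reached an unadjusted p under 0.05. With chip as a block 62 genes passed (15 up, 47 down), on chip 1 alone 1 gene and on chip 2 alone 0 genes (523 at an unadjusted p under 0.05). The count was 13 without Basal-total replicate 2 and 14 without Ox-total replicate 3. Median scaling gave 16 genes (6 up, 10 down) and the authors' values 49 (5 up, 44 down). The 3 other passing probes of Tardbp had changes from -0.21 to -0.01. The antioxidant call ended without a filter on dim probes (adjusted p = 0.379), without replicate 1 (0.0546) or 2 (0.119) and on chip 2 (0.216). The p53 call ended without that filter (0.0544), without replicate 1 (0.0546) or 3 (0.0713) and on chip 1 (0.0865).

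Comparing Basal-ARP with Basal-total asks which transcripts were over- or under-represented among captured RNA of unstressed cells. Of 8072 genes 2619 changed, 1321 up and 1298 down, 98 of them by 2-fold or more (25 up, 73 down). Mid1, which encodes a microtubule-associated ubiquitin ligase, was detected on 4 captured arrays and 0 total arrays and was at least 4.08-fold higher, and the glutamine transporter gene Slc1a5 was at least 2.75-fold higher. Ccdc144b, detected on 1 total array, rose by 2.30 ± 0.21, the transcription factor gene Sox9 by 1.86 ± 0.15 (adjusted p = 2.4e-07) and Plpbp, a pyridoxal phosphate binding protein gene, by 1.45 ± 0.12. Dctn1, which encodes the largest subunit of dynactin, was detected on all total arrays and 0 captured arrays and was at least 6.26-fold lower (adjusted p = 1.6e-13).

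Other raised genes were Atxn3, a deubiquitinase gene mutated in Machado-Joseph disease (1.29 ± 0.08), the dynein gene Dync1li1 (1.29 ± 0.12), Cyp20a1 (1.26 ± 0.17) and Mzt1, a gamma-tubulin complex gene (1.22 ± 0.19). Among lowered genes, the microtubule-associated protein gene Map1b fell by 2.24 ± 0.27 and the synaptic gene Cplx2 by 1.86 ± 0.18, and the netrin receptor gene Unc5b was 2.83-fold lower. The X-inactivation RNA Xist fell by 1.60 ± 0.30, Tmem256 by 1.69 ± 0.17, Cox7a2 by 1.49 ± 0.13 and the cell cycle inhibitor gene Cdkn2a by 1.47 ± 0.14. The sulfurtransferase gene Mpst, detected on 1 captured array, was 2.82-fold lower and Mia3 at least 1.61-fold. Gapdh (0.09 ± 0.08) and Actb (0.06 ± 0.08) did not pass.

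The lists of genes for the respiratory chain, for histones and for both kinds of ribosome lay low among captured RNA. Many of their members did not pass, and the lists passed with the preset correlation only. Of 72 nuclear encoded respiratory chain genes 1 rose, 41 fell and 30 did not pass (2 and 42 adjusted over the list alone; median -0.45), with Ndufa2 at -1.14 ± 0.07, Atp5l at -1.45 ± 0.10 and Uqcr11 at -1.36 ± 0.10. Of 34 histone genes 2 rose and 23 fell (2 and 23 adjusted over the list alone; median -0.51), including H3c6 (-0.73 ± 0.14), H3c1 (-0.66 ± 0.12) and H4c12 (-0.66 ± 0.13). Of 70 mitochondrial ribosomal genes 9 rose and 34 fell (9 and 38 adjusted over the list alone; median -0.27), including Mrps18c (-1.30 ± 0.12) and Mrpl33 (-1.20 ± 0.11). Of 59 cytosolic ribosomal genes 3 rose and 21 fell (3 and 24 adjusted over the list alone; median -0.23), with Rpl36a at -1.24 ± 0.14, Rpl34 at -0.91 ± 0.10 and Rpl39 at -0.78 ± 0.10, whereas Rps15a rose by 0.67 ± 0.09. Their adjusted p-values were 5.9e-14, 2.0e-05, 3.5e-06 and 9.6e-05, and 0.25 for each with an estimated correlation. Medians on chips 1 and 2 were -0.40 and -0.46 for the respiratory chain, -0.41 and -0.54 for histones, -0.23 and -0.36 for mitochondrial ribosomal and -0.16 and -0.25 for cytosolic ribosomal genes.

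Proteasome subunits (1 up, 14 down of 33; 3 and 15 adjusted over the list alone; median -0.23; Psmb10 -0.83 ± 0.10, Psmb1 -0.80 ± 0.09) and antioxidant enzymes (1 up, 8 down of 21; the same adjusted over the list alone; median -0.15; Gpx4 -0.95 ± 0.15, Sod1 -0.63 ± 0.12) also shifted down. Their adjusted p-values were 0.0033 and 0.017, or 0.25 for both with an estimated correlation, with chip medians of -0.16 and -0.34, and -0.10 and -0.30. Cytosolic heat shock and chaperone genes shifted up (6 up, 0 down of 23; 5 and 0 adjusted over the list alone; median 0.25), with the chaperonin genes Cct6a at 0.57 ± 0.08 and Cct3 at 0.34 ± 0.08. The adjusted p was 0.0093, or 0.35 with an estimated correlation, and the chip medians were 0.24 and 0.31.

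The remaining 20 lists did not pass (adjusted p from 0.0616 to 0.968), although single members did. In the mitosis list 8 of 22 rose and 2 fell (adjusted p = 0.0799), with Top2a at 0.71 ± 0.09 and Aurka at 0.66 ± 0.08. Among apoptosis regulators 7 of 17 rose and 1 fell (adjusted p = 0.0616), with Mcl1 at 0.75 ± 0.11. The base excision repair list went both ways (5 up, 3 down of 25, adjusted p = 0.968): Smug1, a uracil glycosylase gene, rose by 0.95 ± 0.09 and Parp1 by 0.64 ± 0.09, while Nudt1, whose enzyme clears oxidised nucleotides, fell by 0.74 ± 0.12. Tfrc (0.72 ± 0.10), Elavl2 (0.71 ± 0.12), Gata3 (0.54 ± 0.10), Sqstm1 (0.69 ± 0.13) and Phgdh (0.77 ± 0.14) rose, and Snrpg (-1.17 ± 0.09), Snrpd1 (-0.88 ± 0.12), Rpa3 (-0.96 ± 0.09) and Ost4 (-1.46 ± 0.12) fell. With chip as a block 3309 genes passed, on chip 1 alone 1361 and on chip 2 alone 1021. Median scaling gave 687 up and 1262 down and no normalization 78 up and 766 down. The heat shock call ended under both (adjusted p = 0.0691 and 0.0623) and with the authors' values (0.0503), and the antioxidant call on chip 1 alone (0.0701). The long mRNA list passed without a filter on dim probes (0.0203), with the mean of a gene's probes (0.045), on chip 1 (0.0054), without replicate 3 (0.00412) and with array weights (0.0327, chosen after seeing the data). Its median was negative each time. Without that filter the apoptosis, translation factor and tubulin and actin lists passed too (0.0231, 0.0354 and 0.0354), translation factors also on chip 1 (0.0446). Zinc finger proteins passed with no normalization (0.0486), on chip 2 (0.0497) and with the brightness covariate (0.0345).

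**Figure D2:**
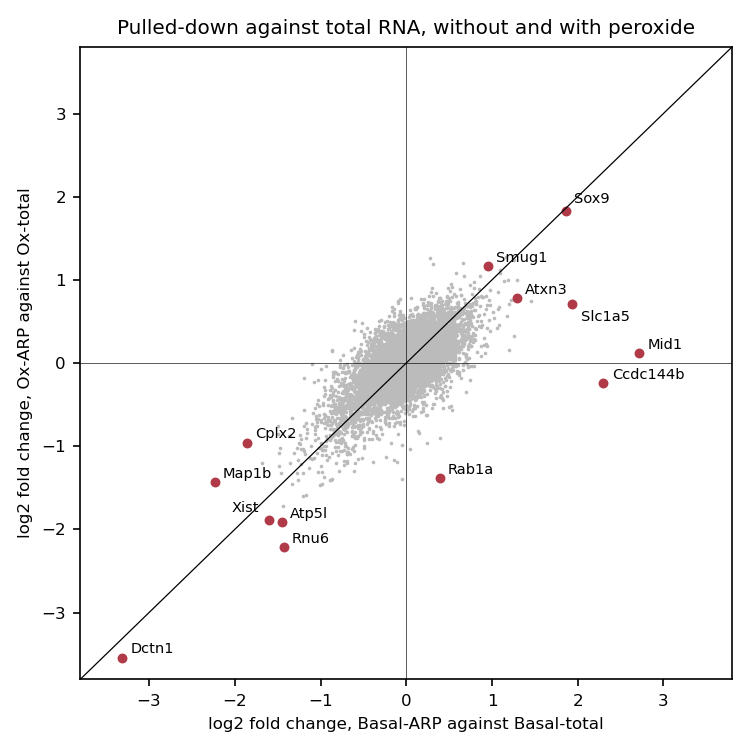
Log2 fold change on capture without peroxide (horizontal axis) and with peroxide (vertical axis), 1 point per tested gene, from limma over 4 arrays per group, with named genes in red and a line of equal change. Dctn1 and Sox9 lie far out in the same direction on both axes, and Mid1 and Ccdc144b far out on the horizontal axis only.

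Comparing Ox-ARP with Ox-total asks the same of peroxide-treated cells. Of 8072 genes 2092 changed, 1091 up and 1001 down, 99 of them by 2-fold or more (15 up, 84 down). Sox9 rose by 1.83 ± 0.15 (adjusted p = 2.0e-07), Heatr3 by 1.27 ± 0.09, the methyl-cycle enzyme gene Ahcy, detected on 1 total array, by 1.26 ± 0.20 and the uracil glycosylase gene Smug1 by 1.17 ± 0.09. Dctn1 was again below detection in captured RNA, at least 6.3-fold lower (adjusted p = 5.3e-14), the spliceosomal small nuclear RNA Rnu6 had -2.21 ± 0.11, the ATP synthase gene Atp5l -1.92 ± 0.10 and Xist -1.89 ± 0.30, all called.

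Further raised genes were Cyp20a1 (1.24 ± 0.17), Zfp763 (1.20 ± 0.16), the chromatin remodelling gene Mta2 (1.15 ± 0.09) and Tomm70a, a receptor for mitochondrial protein import (1.12 ± 0.13), with Ctcfl at least 1.47-fold and Lrrn4cl at least 1.74-fold higher. Further lowered genes were Wfdc12 (-1.60 ± 0.10), the Sm core gene Snrpg (-1.58 ± 0.09), the poly(A) polymerase gene Papola (-1.46 ± 0.19) and Map1b (-1.43 ± 0.27), with the cyclin gene Ccnk at least 1.69-fold and the polarity gene Mpp5 at least 1.76-fold lower. Sec61b, a subunit of the translocon, fell by 1.41 ± 0.10, Rpa3 by 1.37 ± 0.09 and Ost4 by 1.32 ± 0.12.

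The respiratory chain list again lay low (4 up, 39 down of 72; 4 and 41 adjusted over the list alone; median -0.41), with Uqcrh at -1.31 ± 0.08 and Ndufs4 at -1.24 ± 0.08. Histone genes (1 up, 20 down of 34; 1 and 21 adjusted over the list alone; median -0.54) included H4c6 at -1.16 ± 0.12 and H3c6 at -0.93 ± 0.14. Mitochondrial ribosomal genes (4 up, 33 down of 70; 5 and 35 adjusted over the list alone; median -0.30) included Mrpl33 at -1.32 ± 0.11 and Mrps11 at -1.05 ± 0.10. Cytosolic ribosomal genes (2 up, 24 down of 59; 5 and 27 adjusted over the list alone; median -0.23) included Rps27 at -1.06 ± 0.12 and Rps7 at -0.91 ± 0.10, with Rpl22 raised by 0.91 ± 0.11. Adjusted p-values were 4.8e-16, 5.1e-10, 3.2e-07 and 7.3e-05, or 0.131, 0.131, 0.196 and 0.196 with an estimated correlation. Chip medians were -0.48 and -0.37, -0.65 and -0.41, -0.29 and -0.29, and -0.23 and -0.14 in the same order.

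Heat shock and chaperone genes shifted up (11 up, 0 down of 23; 12 and 0 adjusted over the list alone; median 0.45), with Cct6a at 0.59 ± 0.08 and the co-chaperone genes Fkbp4 at 0.49 ± 0.11 and Stip1 at 0.47 ± 0.11. The list's adjusted p was 0.0002, or 0.196 with an estimated correlation, and its chip medians were 0.42 and 0.43. Translation factors shifted up (11 up, 4 down of 40; 14 and 4 adjusted over the list alone; median 0.17; Eif3b 0.58 ± 0.10, Eif3f 0.43 ± 0.08). The adjusted p was 0.0393, or 0.131 with an estimated correlation, and chip medians were 0.18 and 0.19. Antioxidant enzymes (1 up, 3 down of 21; the same adjusted over the list alone; median -0.20; Gpx1 -0.74 ± 0.13, Gpx4 -0.67 ± 0.15) and proteasome subunits (1 up, 9 down of 33; the same adjusted over the list alone; median -0.10; Psmd5 -1.17 ± 0.13, Psmb10 -0.93 ± 0.10) shifted down. Their adjusted p-values were 0.0282 and 0.0464, or 0.196 and 0.418 with an estimated correlation, and chip medians were -0.15 and -0.15, and -0.12 and -0.19.

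The other 19 lists did not pass (adjusted p from 0.141 to 0.955), among them base excision repair (6 up, 1 down of 25; Parp1 0.82 ± 0.09). The proteasome call ended with the replicate number as a block within treatment (adjusted p = 0.117) or across it (0.0621), with chip as a block (0.0546), on chip 1 (0.139), with the brightness covariate (0.0739) and without replicate 2 (0.078), 3 (0.0956) or 4 (0.0561). That of translation factors ended with median scaling (0.392), no normalization (0.449), cyclic loess (0.24), the authors' values (0.423) and the mean of a gene's probes (0.185), on chip 1 (0.0899) and without replicate 4 (0.059). That of antioxidant enzymes ended with the mean of a gene's probes (0.0576). With the pairing of captured with total arrays 3279 genes passed (1789 up, 1490 down), with chip as a block 2700, on chip 1 alone 1168 and on chip 2 alone 550. The authors' values gave 1629 up and 815 down and no normalization 158 up and 347 down. A second probe of Heatr3 had -0.04, and Eif3b turned to -0.12 with the mean of its probes.

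Capture effects with and without peroxide ran in parallel for most called genes. In both comparisons 571 genes rose, against 178.5 for independent lists of those sizes, 629 fell, against 161.0, and 26 moved in opposite directions. Over all tested genes, which are not independent replicates, Pearson's r was 0.68 and Spearman's rho 0.61. The 2 comparisons share no arrays, though both may carry the array positions of their groups. The number of genes called in the same direction in both was 1200, against 332 with no normalization and 584 and 324 on chips 1 and 2 alone.

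**Figure D3:**
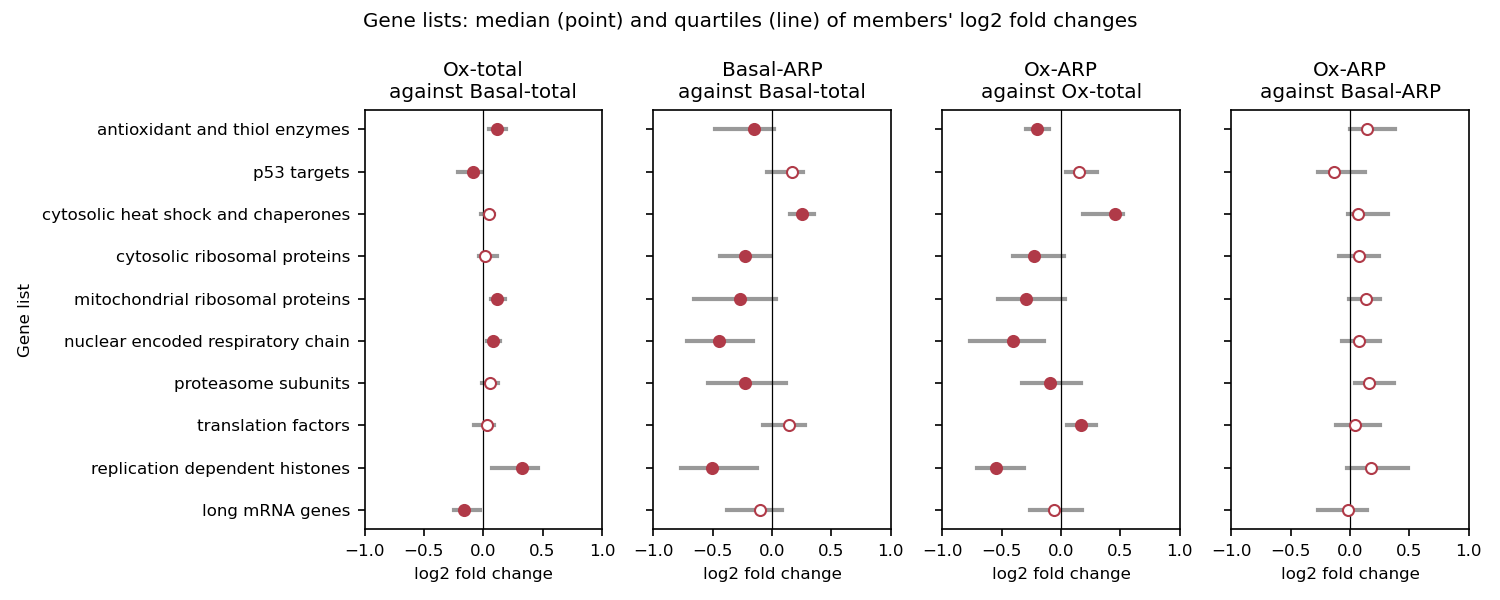
Log2 fold changes of the members of the 10 gene lists that passed camera in any comparison, with the median as a point, quartiles as a line, and 1 panel for each of the 4 comparisons between groups. Filled points mark lists that passed with the preset correlation. Respiratory chain, histone and both ribosomal lists lie below 0 on capture with and without peroxide, with medians from -0.54 to -0.23.

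Comparing Ox-ARP with Basal-ARP asks how captured RNA differed with peroxide. Here 2216 genes changed, 1123 up and 1093 down, 55 of them by 2-fold or more (4 up, 51 down). Mid1 (at least 4.13-fold lower, adjusted p = 4.4e-07) and Ccdc144b (at least 3.68-fold lower) were detected on 4 Basal-ARP arrays and 0 Ox-ARP arrays. Rab1a, whose GTPase directs traffic from the endoplasmic reticulum to the Golgi, fell by 1.98 ± 0.13 (adjusted p = 8.9e-08), Rps15a by 1.58 ± 0.09 and the thioesterase gene Lypla1 by 1.54 ± 0.12. Vat1 rose by 1.22 ± 0.17 and the neurotrophic factor gene Metrn by 0.96 ± 0.12.

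Also raised were Gipc1 (1.08 ± 0.29, adjusted p = 0.00998), Pebp1, the Raf kinase inhibitor gene (0.96 ± 0.13), the lysosomal transporter gene Slc15a4 (0.95 ± 0.17), the pyridoxal phosphatase gene Pdxp (0.95 ± 0.11) and Pmm1, a phosphomannomutase gene (0.90 ± 0.12), with Bco1 at least 1.49-fold higher. Also lowered were Marchf11 (-1.55 ± 0.27), the rhomboid protease gene Rhbdl2 (-1.52 ± 0.13) and Erich5 (-1.41 ± 0.16). The cyclin gene Ccne2 fell by 1.24 ± 0.13, the replicative helicase gene Mcm7 by 1.15 ± 0.14 and Top2a by 0.71 ± 0.09, while the DNA replication list (3 up, 5 down of 33, adjusted p = 0.885) and the mitosis list (3 up, 3 down of 22, adjusted p = 0.464) went both ways. The neurodegeneration list went both ways, with 5 of 26 raised and 4 lowered, including Aplp1 (0.76 ± 0.12), Atxn3 (-0.76 ± 0.08) and Tardbp (-0.71 ± 0.12 on its brightest probe).

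In this comparison 0 of 27 lists passed camera, 7 at an unadjusted p under 0.05 (adjusted p from 0.0868 to 0.973). The 3 lists nearest to passing, each with an adjusted p of 0.0868, were mitochondrial ribosomal genes (12 up, 2 down of 70; median 0.14; Mrpl46 0.63 ± 0.08), proteasome subunits (5 up, 2 down of 33; median 0.16; Psmd5 -1.31 ± 0.13) and zinc finger proteins (13 up, 26 down of 155; median -0.10; Zfp597 -0.79 ± 0.09). With an estimated correlation their adjusted p-values were 0.831, 0.763 and 0.763. Antioxidant enzymes had 7 of 21 raised and 0 lowered (8 and 0 adjusted over the list alone; Sod1 0.44 ± 0.12; adjusted p = 0.182), and histones 6 of 34 raised and 0 lowered (H3c1 0.41 ± 0.12; adjusted p = 0.171). In the secretory list 11 of 31 rose and 3 fell (Ganab 0.72 ± 0.09; adjusted p = 0.181). Among splicing factors 2 of 41 rose and 10 fell (Hnrnpk -0.99 ± 0.13; adjusted p = 0.182), and in the stress and unfolded protein response list 7 of 24 rose and 4 fell (Hyou1 0.75 ± 0.11, Phgdh -0.95 ± 0.14). Hmox1 (0.12 ± 0.10), Srxn1 (0.10 ± 0.12), Cdkn1a (0.09 ± 0.12) and Fos (-0.34 ± 0.13, adjusted p = 0.056) did not pass.

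With median scaling the split was 1805 up and 418 down, and with no normalization 836 up and 101 down (authors' values 2154 genes). The mitochondrial ribosomal, proteasome and zinc finger lists passed with median scaling (adjusted p = 0.0156, 0.0329 and 0.0164), no normalization (0.0158, 0.0441 and 0.0158), the authors' values (0.0409, 0.0409 and 0.0446), no filter on dim probes (0.00565, 0.00414 and 0.0433) and on chip 2 alone (0.00964, 0.0178 and 0.0109). The zinc finger median was 0.01 with median scaling, against 0.14 for all genes, and 0.06 against 0.20 with no normalization. The mitochondrial ribosomal and zinc finger lists also passed without replicate 2 (0.0247 and 0.0263) and with the brightness covariate (0.0246 and 0.0168). Glycolysis passed with no normalization (0.0158) and that covariate (0.0246), histones without replicate 2 (0.0247) and on chip 2 (0.0055), and the respiratory chain and long mRNA lists on chip 2 (0.0105 and 0.0362). With chip as a block 2955 genes passed, and 712 and 717 on chips 1 and 2 alone. A second passing probe of Lypla1 had 0.18, and the 4 probes of Gipc1 had 1.08, 0.69, -0.16 and -0.54.

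The 25 genes that changed in total RNA were set against the captured fractions. Of these, 1 rose and 17 fell in both, against 0.70 and 2.71 for independent lists, 0 moved in opposite directions, and 23 had the same sign. Rps15a fell by 1.11 ± 0.09 in total and 1.58 ± 0.09 in captured RNA, and Tardbp by 0.71 ± 0.12 in each on its brightest probe. The other passing probes of Tardbp had smaller changes in total RNA. Over all genes r was 0.51 and rho 0.48, a value to which the pairing of captured with total arrays can add. The number of calls shared in direction was 18, against 11 with median scaling, 37 with the authors' values, 44 with chip as a block, and 1 and 0 on chips 1 and 2 alone.

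The interaction asks whether peroxide altered the effect of capture itself. The difference passed for 126 genes, 56 positive and 70 negative, 18 of them by 2-fold or more (4 up, 14 down). The most negative named genes were Mid1 (-2.60 ± 0.32, adjusted p = 0.00055) and Ccdc144b (-2.55 ± 0.30), both captured without peroxide and below detection on all Ox-total and Ox-ARP arrays, so that their fitted sizes are not bounds. The same holds for Slc1a5, detected on 0 total arrays, and for Bco1 and Cacng7, each detected on 0 Basal-ARP arrays. Rab1a (-1.77 ± 0.19, adjusted p = 0.00022), the perforin gene Prf1 (-1.35 ± 0.16), Lypla1 (-1.29 ± 0.18), Slc1a5 (-1.23 ± 0.22), the mitotic kinase gene Melk (-1.104 ± 0.21) and Erich5 (-1.09 ± 0.22) followed. The most positive were Bco1 (1.104 ± 0.18), Metrn (1.03 ± 0.16), Elfn2 (1.02 ± 0.20), Vat1 (1.01 ± 0.24, adjusted p = 0.04), Pebp1 (0.91 ± 0.18), Cuedc1 (0.90 ± 0.13) and the calcium channel subunit gene Cacng7 (0.84 ± 0.16).

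Among cell cycle genes Ccne2 (-1.04 ± 0.18), Mcm7 (-0.97 ± 0.19), Top2a (-0.72 ± 0.13) and Plk1 (-0.58 ± 0.12) passed, all negative, but neither the DNA replication list (0 up, 2 down of 33, adjusted p = 0.947) nor the mitosis list (0 up, 2 down of 22, adjusted p = 0.323) did. Psmd5 (-1.03 ± 0.19), Fos (-0.73 ± 0.18, adjusted p = 0.048), Zfp597 (-0.73 ± 0.13), Ncoa4 (-0.63 ± 0.14) and Atxn3 (-0.51 ± 0.12) passed as negative, and Ganab (0.69 ± 0.13), Mrpl46 (0.56 ± 0.12) and Cebpb (0.48 ± 0.11) as positive. Of 27 lists 0 passed camera, 3 at an unadjusted p under 0.05. The lowest adjusted p was 0.227, shared by histones, zinc finger proteins and the secretory list (0.686 the lowest with an estimated correlation). Histones passed with median scaling (adjusted p = 0.0284), without a filter on dim probes (0.00603), on chip 1 (0.00455) and without replicate 3 (0.00518), each time with a negative median, and zinc finger proteins on chip 2 (0.00647).

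The count of 126 moved with single arrays left out, and rose to 170 without Basal-ARP replicate 1. It was 60 without Basal-total replicate 1, 70 without Basal-total replicate 4, 79 without Ox-total replicate 1 and 56 without Ox-total replicate 3. It was 72 without Basal-ARP replicate 2, 76 without Ox-ARP replicate 2 and 68 without Ox-ARP replicate 4. It was 964 (511 up, 453 down) with the replicate number as a block within treatment, 528 with chip as a block, 3 on chip 1 and 0 on chip 2 (limma; 990 and 883 at an unadjusted p under 0.05). Median scaling gave 131 up and 31 down, and 5 of 100 drawn labellings of the arrays, the real one included, gave as many genes. The 4 others that did so break up pairs of captured and total arrays, but so do nearly all the labellings that gave 0 genes. Of the 35 splits of the 8 paired differences, the real one gave 964 genes and the highest other 19.

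**Figure D4:**
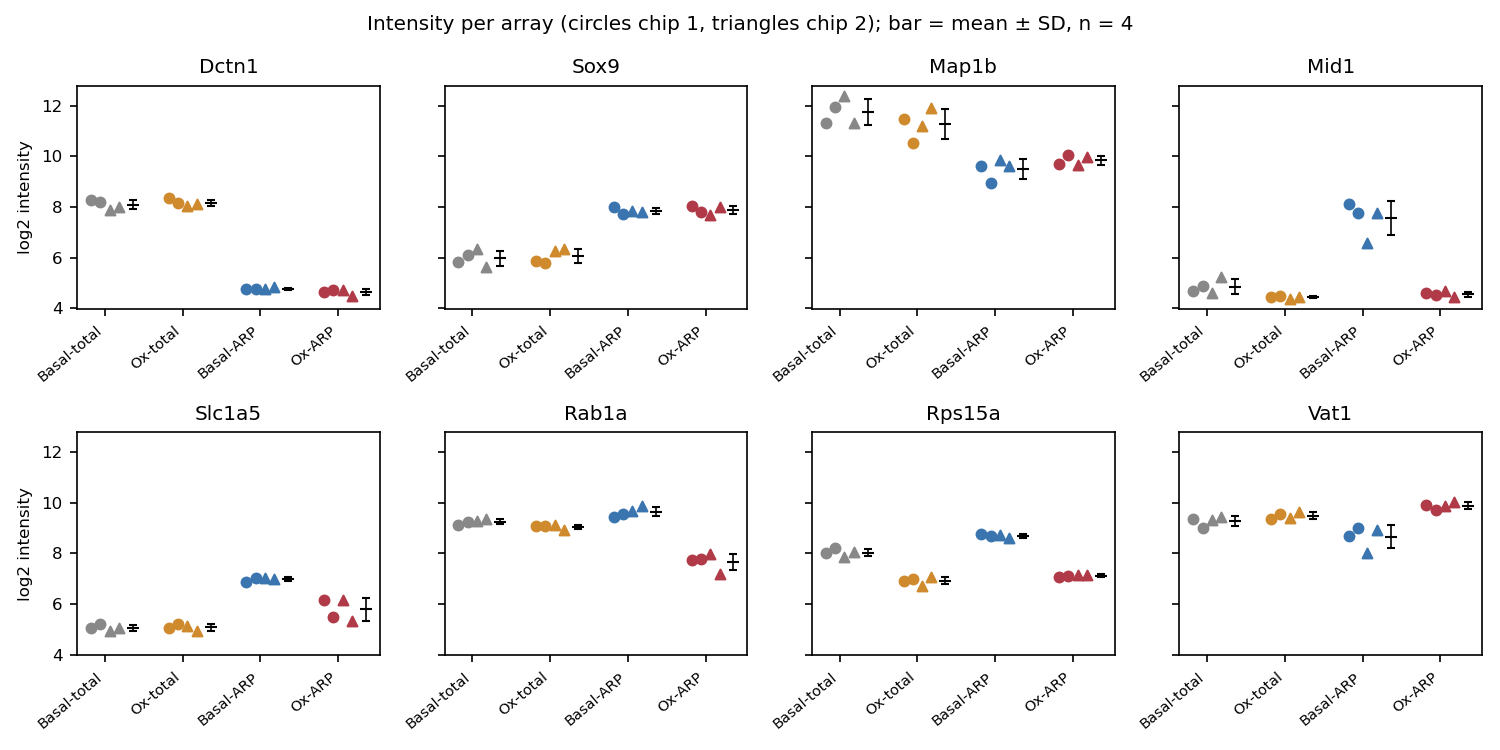
Normalized log2 values of 8 genes on each array by group, with circles for arrays on chip 1, triangles for those on chip 2 and bars for the group mean and SD (n = 4). Dctn1 is low in both captured groups, Mid1 is high in Basal-ARP only, and Rps15a is lower in both peroxide groups.

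Among lists for other cell types, the macrophage and blood cell, glial and epithelial lists had too few members to test, and fibroblast markers had 3 tested members. On capture 0 rose and 1 fell without peroxide, and 0 and 0 with it, and 2 rose and 0 fell in Ox-ARP against Basal-ARP (adjusted p = 0.439). Neuronal identity genes, tubulins and actin genes, iron handling, cholesterol synthesis, glycolysis and immediate early genes passed in none of the 5 comparisons as designed, at the preset correlation (lowest adjusted p 0.634, 0.233, 0.613, 0.693, 0.141 and 0.306), with Slc2a1 at 0.37 ± 0.10 after peroxide in total RNA (adjusted p = 0.19). Of these, glycolysis and the tubulin and actin list passed under other settings, including no filter on dim probes for the latter on capture without peroxide and the brightness covariate for the former in both comparisons of peroxide. NRF2 targets, neurodegeneration, DNA replication and the stress and unfolded protein response list passed in none either (lowest adjusted p 0.495, 0.361, 0.879 and 0.257).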

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

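The test of the 8 pair differences and the test of array position were chosen only after the results were seen. The other tests of this part were set before they were run. Those of changes carried over from total RNA and of spread address a difference in counts that comes from these results.

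Regrouping the arrays asked whether chance could give as many changed genes. For each comparison of 2 groups, 1 of the 35 splits of its 8 arrays, the real one, gave as many genes. That is the lowest share that 35 splits can give, so chance is argued against only to that extent. The real counts and the highest of the other splits were 25 and 2 in Ox-total against Basal-total, 2619 and 515 in Basal-ARP against Basal-total, 2092 and 1 in Ox-ARP against Ox-total, and 2216 and 1 in Ox-ARP against Basal-ARP. Where the numbers pair captured with total arrays, only 8 splits, the real one included, part all pairs. The highest among the others of these was 0 in both capture comparisons. The split that follows the chips gave 0 (limma) in each comparison. For the interaction, 5 of 100 drawn labellings gave as many as the real 126, with 641 the highest, so chance is not excluded for the count from the fit without pairs. The 4 besides the real one break up pairs of captured and total arrays. Nearly all the labellings that gave 0 genes do so too, so broken pairs do not set these 4 apart. Of these, 2 (209 and 641 genes) left all 8 captured arrays as they were, so that the peroxide difference among those arrays entered the interaction. The others (317 and 407 genes) left 6 and 4 captured arrays as they were, and that account does not cover them. Counts of several times the real one point to a structure of the samples, whose source was not tested. With the pairs kept, the 8 differences between captured and total arrays gave 964 genes when split by treatment. Of their 35 splits 1, the real one, gave as many, with 19 the highest other, the lowest share that 35 splits can give. The test was chosen after the unpaired result was seen and rests on a pairing read from the same values. It therefore does not exclude chance for the paired count.

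More genes changed with peroxide among captured fractions (2216) than among total RNA (25), and 3 technical explanations were weighed. If changes in transcript level had carried over at their full size, genes called on 1 chip would show the same change in total RNA of the other chip, but the total RNA change was 30.5% of the captured change at most (26.5% on the other chip), which argues against this as the whole source. A larger spread between total arrays is also argued against, since the median SD within total groups was 0.95 of that within captured groups. Array position and the batch of the bead capture cannot be told apart from the groups, because 0 positions held more than 1 group. A difference in which transcripts carried ARP label after peroxide stays open, as a hypothesis.

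In 35 of 624 groups of 4 arrays tested, 1 array lay apart from the other 3 by more than Dixon's 95% critical value for the ratio of its gap to the group's range, against 31.2 expected since chance gives about 1 in 20. Basal-total replicate 3 was that array in 9 of them. Its mean signal was high (533 against 403 for the others, ratio 0.848), and it was high for Xist (0.838) and Prdx1 (0.856) and low for Ddit3 (0.844), Mpst (0.919), Ost4 (0.851), Ahcy (0.936), Ncoa4 (0.863) and Ret (0.863). Other Basal-total arrays lay apart for Lrrc29 (0.901), Zbtb2 (0.892) and Ank2 (0.859). In Ox-total this held for H4c6 (0.892), Slc2a1 (0.982), Cyp20a1 (0.869), Uqcr11 (0.91), Psmb10 (0.844), Ost4 (0.92) and Pdxp (0.883). In Basal-ARP it held for the p53 target list (0.887), H2bc18 (0.967), Slc2a1 (0.877), Papola (0.895), Rps7 (1), Gipc1 (0.859) and Elfn2 (0.861). In Ox-ARP it held for Nfkbiz (0.832), Zfhx3 (0.873), Mrps10 (0.976), Cdkn2a (0.853), Gpx1 (0.985), Lrrn4cl (0.835), Gipc1 (0.869), Pebp1 (0.938) and Lypla1 (0.866).

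Over all tested genes the interaction in limma passed for 126 of 8072, in the fit without pairs for which chance is not excluded. The rule for the genes named picks the most changed of these, which raises their share among named genes. The effect of capture was called different with peroxide for 34 of 144 named genes. It was lower with peroxide for Mid1 (-2.60), Ccdc144b (-2.55), Rab1a (-1.77), Prf1 (-1.35), Lypla1 (-1.29), Slc1a5 (-1.23), Melk (-1.104), Erich5 (-1.09), Ccne2 (-1.04), Psmd5 (-1.03), Mcm7 (-0.97), Rhbdl2 (-0.80), Rnu6 (-0.78), Fos (-0.73), Zfp597 (-0.73), Top2a (-0.72), Plpbp (-0.70), Ncoa4 (-0.63), Plk1 (-0.58), Zbtb2 (-0.51) and Atxn3 (-0.51). It was higher for Bco1 (1.104), Metrn (1.03), Elfn2 (1.02), Vat1 (1.01), Pebp1 (0.91), Cuedc1 (0.90), Cacng7 (0.84), Pmm1 (0.80), Pdxp (0.72), Ganab (0.69), Prr15 (0.67), Mrpl46 (0.56) and Cebpb (0.48). The sizes for Mid1, Ccdc144b, Slc1a5, Bco1, Cacng7 and Prr15 are fitted values and not bounds, since at least 1 group had 0 arrays with the gene detected (Ox-total and Ox-ARP for Prr15).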

How the results depend on the processing

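The alternatives with array brightness, array weights and the replicate block within treatment were chosen only after seeing the data; the others were planned. Counts are given in the order Ox-total against Basal-total, Basal-ARP against Basal-total, Ox-ARP against Ox-total, Ox-ARP against Basal-ARP and interaction. No normalization gave 1, 844, 505, 937 and 5 genes, and moved the median of all genes, against that with quantile normalization, by -0.12 in the second, 0.17 in the fourth and 0.13 in the last; median scaling moved the fourth by 0.12. Chip 1 alone gave 1, 1361, 1168, 712 and 3, and chip 2 alone 0, 1021, 550, 717 and 0, with fewer arrays. The brightness covariate gave 169, 4069, 3159, 3620 and 1126, and a 2-fold minimum 4, 98, 99, 55 and 18. In the first comparison median scaling gave 16, the authors' values 49, detection on all arrays 10, chip as a block 62 and array weights 89; in the interaction the authors' values gave 218, chip as a block 528 and array weights 481. The replicate block gave 84 and 684 in these, and 3500, 2870 and 3117 in the others; within treatment it gave 3851 in the second, 3279 in the third and 964 in the interaction. It ended no list call but that of the proteasome in Ox-ARP against Ox-total. The cause of these differences was not tested.

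Leaving out 1 replicate number gave 4 to 19, 1447 to 2233, 1091 to 1866, 1068 to 1716 and 5 to 54 genes, the lowest without replicate 2 except in the fourth (replicate 4). Single arrays left out gave 13 to 28, 2129 to 2640, 1677 to 1961, 1579 to 2242 and 56 to 170. The number of shared capture calls, 1200, was 332 with no normalization, 584 and 324 on chips 1 and 2, and 597 to 1020 with a replicate number left out. The number of shared treatment calls, 18, was 11 with median scaling, 1 with no normalization, 37 with the authors' values, 8 with detection on all arrays, 44 with chip as a block, 1 and 0 on the chips, and 4 to 15 with a number left out. All 21 list calls (7 up, 14 down) were lost with an estimated correlation, leaving 0 (camera), and were 19 to 22 with a number left out.

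Direction turned for 8 gene results, all but 1 with the mean of a gene's probes: Prdx1 (0.0853) and Tyms (0.0908) in Basal-ARP against Basal-total, Eif3b (-0.12) and Tubb2b (-0.0405) in Ox-ARP against Ox-total, and Pfkm (-0.0456), Uros (-0.0167) and Ret (-0.0648) in Ox-ARP against Basal-ARP. With no normalization Tubb2b in Basal-ARP against Basal-total was -0.0083. Probes near background limit the depth of these arrays, since the offset draws their folds towards 0.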

Other observations

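The tests on list medians, on mean expression and on genomic span of the lists, and the families, were chosen only after the results were seen. The tests of array splits and of normalization for genomic span were set before they were run, for a trend that comes from these results.

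Gene families defined by a shared symbol stem were tested with camera, 107 families with at least 8 tested members. Only Psmb, Lsm and Timm are described, all low on capture, and the Psmb genes are also members of the proteasome list. The beta subunits of the proteasome (Psmb, 9 genes) lay low on capture, with a median of -0.60 and 7 lowered without peroxide and a median of -0.34 and 4 lowered with it (adjusted p = 0.00613 and 0.00897, or 0.622 and 0.598 with an estimated correlation), and with medians below 0 under every scaling run. Psmb1 had -0.80 and -0.53, and Psmb6 -0.74 and -0.51, whereas Psmb2 had 0.31 and -0.02 and did not pass. The 12 genes of the Lsm stem, which hold members of the Lsm rings of RNA binding proteins and also Lsm10, Lsm11, Lsm12, Lsm14a and Lsm14b, had a median of -0.30 with peroxide and 5 lowered (adjusted p = 0.023, or 0.247 with an estimated correlation), and of -0.40 without it, with 1 raised and 6 lowered (adjusted p = 0.135); without and with peroxide Lsm5 had -0.81 and -0.85 and Lsm7 -0.70 and -1.07, whereas Lsm14a had 0.54 (raised) and 0.26 and Lsm6 0.22 and 0.27. The Timm genes of mitochondrial protein import (12 genes) had medians of -0.20 with 4 lowered and -0.22 with 3 lowered (adjusted p = 0.038 and 0.0497, or 0.55 and 0.267 with an estimated correlation), led by Timm8b (-1.27 and -1.32) and Timm10 (-0.82 and -1.05), while Timm17b and Timm44 had 0.22 and 0.15 with peroxide and did not pass. Lsm and Timm medians also stayed below 0 under every scaling run. These genes were chosen after their values were seen.

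Respiratory chain, histone and both ribosomal lists lay low in captured RNA with and without peroxide. Over the other settings the list median nearest to that of all genes was at -0.242 relative to it, without background correction, which keeps quantile normalization. With cyclic loess the nearest was -0.283, for the mitochondrial ribosomal list in Basal-ARP against Basal-total. A shift of all genes alike cancels in this measure, so median scaling and no normalization gave identical values. Scaling is argued against as the source only of the lists' position relative to other genes. Mean expression is argued against too, as every list lay at the lowest percentile (0) of 10000 random lists matched on mean expression. That match is coarse, by equal groups of genes, so lists of very bright genes may be matched with dimmer ones. The lists were also picked because they lay low in these comparisons. Matching on genomic span put the respiratory chain and the mitochondrial ribosomal list at percentile 0, which argues against span for them. Both kinds of random list treat genes as independent, so these percentiles hold only as far as list members vary independently. Histones lay at 0.01 in Basal-ARP and 0 in Ox-ARP. Their median span was 0.488 kb, against a median of 5.12 kb in the shortest of 4 equal groups of genes. The matched genes may thus have been longer, so span cannot be told apart for histones. The cytosolic ribosomal list lay at 6.45 in Basal-ARP and 1.05 in Ox-ARP, so span cannot be told apart for that list either. Transcript length itself was not analysed here, and short mRNAs that offer fewer ARP sites may be one explanation, as a hypothesis that was not tested. Values that bear on length went both ways. Longer genomic span went with higher values on capture without peroxide (rho 0.242). The long mRNA list, where it passed there under other settings, had negative medians (-0.21 on chip 1 alone), which that explanation would not give.

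Genes of longer genomic span tended to be lower in total RNA after peroxide (Spearman's rho -0.294 across 7460 genes, which are not independent replicates; -0.29 and -0.22 on chips 1 and 2). Chance is not excluded, since 2 of 35 splits of the 8 arrays gave a rho as far from 0, with 0.303 the highest other. Over the other settings the rho nearest to 0 was -0.299, without background correction, which keeps quantile normalization. With cyclic loess rho was -0.306 and with the authors' values -0.32, which argues against scaling. Median scaling and no normalization differ by a shift of all genes alike and gave the same rho (-0.325). Mean expression is argued against by a rho of -0.302 given mean expression. Without Basal-total replicate 3 rho was -0.195. The correlation was -0.243 between the captured fractions (-0.146 and -0.305 on chips 1 and 2, and -0.157 without Basal-ARP replicate 3), and positive on capture (0.242 without and 0.162 with peroxide); comparisons that share arrays share their chance values.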
